A study of Homo sapiens with 9 samples.

How the data were processed

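RNA sequencing of total RNA from Huh7 human hepatocellular carcinoma cells was examined in 9 libraries, 3 from cells given vehicle and 3 each from cells given 5 uM FIDAS-5 or 0.5 uM JQ1 for 48 h. RNA was extracted with silica columns and libraries were prepared by a commercial provider, per the labels' protocols. The deposited values are TPM per gene symbol, made by the authors with Salmon against genome build hg38, per the submitters' processing notes; neither the Salmon version nor the annotation is stated. Each library sums to 1000000 over all listed symbols to within 2 TPM. TPM keeps no read counts, so the depth per library, the counting error and the lowest detectable level are unknown.

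Gene symbols were matched to a RefSeq annotation of the same genome build for biotype and coordinates: 25681 as current symbols, 1134 as synonyms and 985 not at all. Values were transformed to log2(TPM + 1). A pseudocount of 1 makes fold changes of genes at a few TPM smaller than the ratio of their means. Genes with at least 1 TPM in at least 3 of the 9 libraries were kept (13573 genes). A linear model with a mean per group was fitted to all 9 libraries with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation without a trend (6 residual and 2.86 prior degrees of freedom). Each compound was compared with vehicle and JQ1 with FIDAS-5, two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

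Of 42 gene lists, 38 had at least 5 tested members and were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists, and again with the correlation estimated per list. Members were counted as called over all genes and as called when adjusted over the list alone. The comparisons, lists, tests, the rule for naming genes and most other settings were fixed before the data were examined.

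The rule named MAT2A, MAT2B, MAT1A, BRD2, BRD3, HEXIM1 and MYC always. For each compound against vehicle it took the 10 genes that rose and the 10 that fell by the largest log2 fold change, among genes called, with a mean of at least 5 TPM in the higher group, no overlap of libraries between the groups, and a symbol that is not a clone or locus identifier. From each list it took up to 4 members with the smallest adjusted p, and any member could be named to describe its list. Between the compounds it took 5 genes in each direction, and for both compounds 5 that rose, 5 that fell and 5 that went opposite ways, by the largest of the smaller changes. Not every gene that met the rule is printed, and results of some genes are not reported. Genes named in the closing section from families of symbols, and RN7SK, MIR6723 and MIR4461, were chosen after their values were seen.

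Overlap between the compounds was set beside the overlap of independent lists. Correlation and covariance of the fold changes were set beside 100 simulations. In each, all 9 libraries, vehicle included, were drawn anew as random mixtures of the residuals of the 9 libraries, with no group changed. Both simulated treated groups were compared with the same simulated vehicle libraries. The pipeline was tested on simulated data with changes added to 200 genes: 52% of changes of size 1 on the log2 scale and 97% of size 2 were recovered, 5.10% of calls were false, and an unchanged contrast gave 0 calls. The noise was independent between genes, and changes were added only to genes with a mean log2(TPM + 1) over 2. Departures shared by many genes, such as those along GC content, were not simulated. These rates may therefore not hold for the real libraries or for genes at lower levels. Results were recomputed with another pseudocount (0.1), no filter, a stricter filter (5 TPM), median-of-ratios scaling, quantile normalization, only the 6 libraries compared, the replicate number as a block, a trend in the moderation, no mitochondrially encoded genes, limma's fry for lists and leaving out each library in turn. Chosen after the data were seen were protein-coding genes only, removal of a lowess trend on transcript GC content (median over GENCODE transcripts, 12925 of the tested genes), leaving out FIDAS-5 replicate 3 and JQ1 replicate 3 together, and splitting the vehicle libraries between the compounds with 4 group means (5 residual degrees of freedom, the spread taken as equal in a group of 1).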

Results

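RNA was measured in Huh7 cells, an established human hepatocellular carcinoma line, by sequencing of total RNA. The 9 libraries fell into 3 groups of 3. Vehicle-treated cells were the control, and the other groups were treated for 48 h with 5 uM FIDAS-5 or with 0.5 uM JQ1. FIDAS-5 inhibits MAT2A, the enzyme that makes S-adenosylmethionine, the main methyl donor of the cell. JQ1 displaces the BET bromodomain proteins from acetylated histones. The compounds are not analogs of each other and each was given at 1 dose, so their responses are set side by side without a matched dose. The deposited values were TPM (transcripts per 1000000) per gene symbol, and 13573 genes were tested. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

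Protein-coding genes held 27.6 to 34.0% of the TPM of a library. Small RNAs were counted here as structural RNAs plus matched microRNA and ribosomal RNA symbols. They held 49.8% ± 7.79 (SD, n = 3) in vehicle libraries, 42.5% ± 4.78 in FIDAS-5 libraries and 35.2% ± 3.12 in JQ1 libraries. The small nuclear RNA RN7SK alone held 10.7 to 19.1%. MIR6723 and MIR4461, which had no match in the annotation used, together held 17.8% ± 8.80 in vehicle, 26.3% ± 3.26 with FIDAS-5 and 31.9% ± 1.38 with JQ1. Between 12229 and 13014 genes reached 1 TPM in a library. Depth is unknown because TPM keeps none. Pearson correlations across genes within a group were 0.952 to 0.975, and no libraries were identical. The first principal component held 42.9% of the variance and separated JQ1 from the other libraries, and the second held 23.5% and separated vehicle from FIDAS-5. FIDAS-5 replicate 3 and JQ1 replicate 3 departed from their group means together across genes (correlation 0.42), and both departures rose with transcript GC content (Spearman 0.56 and 0.64 across genes). Departures of FIDAS-5 replicate 1 and JQ1 replicate 1 fell with GC content (-0.51 and -0.65). Genes are not independent replicates in these correlations.

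**Figure D1:**
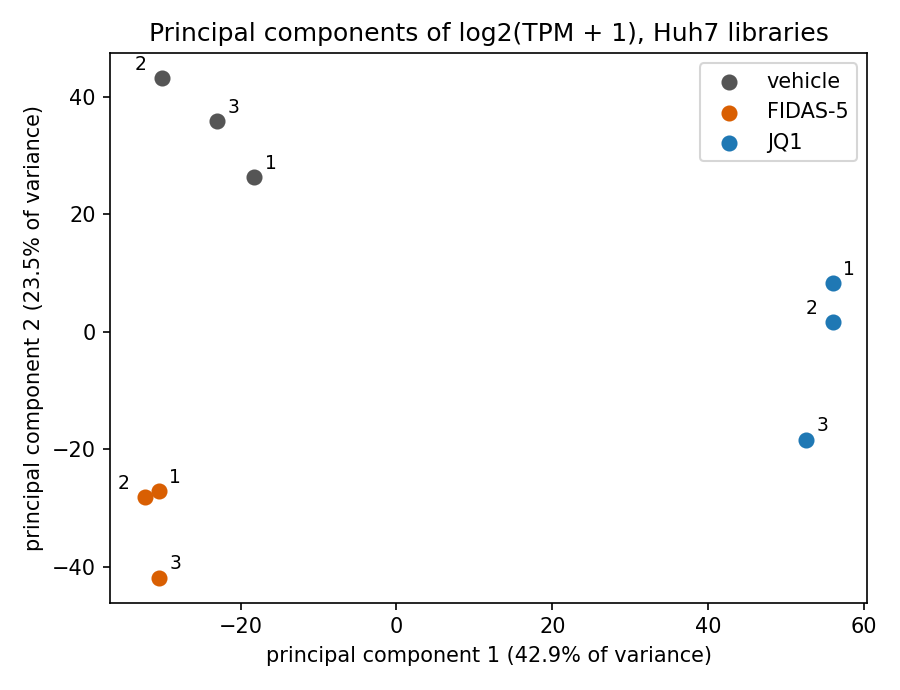
Principal components 1 and 2 of log2(TPM + 1), with 42.9% and 23.5% of the variance on the axes. Each point is a library, coloured by group and numbered by replicate; the 3 JQ1 libraries lie at 52.6 to 56.0 on component 1 and the other 6 at -32.3 to -18.3.

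**Figure D2:**
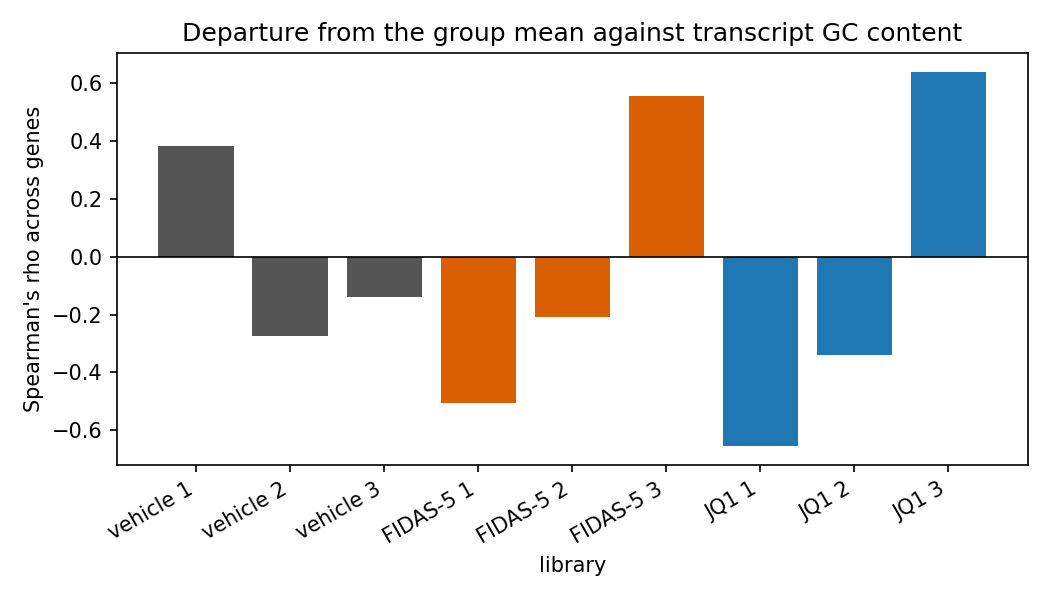
Spearman correlation across genes between each library's departure from its group mean and transcript GC content. Bars are libraries, coloured by group, and run from -0.65 in JQ1 replicate 1 to 0.64 in JQ1 replicate 3.

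The comparison of FIDAS-5 with vehicle asks which transcripts changed with the MAT2A inhibitor. With FIDAS-5, lists of DNA replication, mitosis and histones with polyadenylated transcripts were called lower. Lists of the interferon response, chemokines, apolipoproteins, fatty acid oxidation and drug metabolism were called higher, each with members that were not called. With an estimated correlation between genes none of them was called (smallest adjusted p = 0.104). CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor (AHR), rose from 5.07 ± 0.677 TPM (SD, n = 3) to 985 ± 54.1 TPM, a log2 fold change of 7.35 (SE 0.12, adjusted p = 1.06e-08). The gene lies on chromosome 15 from 74719542 to 74725528. GDF15, a secreted stress cytokine on chromosome 19 (18386158 to 18389176), rose from 11.2 ± 0.969 to 167 ± 21.4 TPM (log2 fold change 3.78, SE 0.14, adjusted p = 4.68e-06). CYP1B1 rose by 4.40 on the log2 scale and IGFBP1, an insulin-like growth factor binding protein, by 3.68. CIDEC, a lipid droplet protein, rose by 3.55, PHLDA2 by 3.08 and the peptide hormone receptor VIPR1 by 3.07. The bilirubin-conjugating enzyme UGT1A1 rose by 3.14 and the aldo-keto reductases AKR1C1 and AKR1C2 by 3.14 and 3.18. These have near-identical relatives, so their separate levels are uncertain.

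MAT2A itself was at 95.5 ± 15.4 TPM in vehicle and 78.7 ± 9.66 TPM with FIDAS-5 (log2 fold change -0.27, SE 0.17, adjusted p = 0.305); it lies on chromosome 2 from 85539168 to 85545281. MAT2B, its regulatory partner, had a log2 fold change of -0.76 (adjusted p = 0.0730). MAT1A, the liver form of the enzyme, rose from 2.33 ± 0.315 to 3.98 ± 0.624 TPM (log2 fold change 0.58, adjusted p = 0.0159; 0.0706 without vehicle replicate 3). With FIDAS-5, BRD2 had a log2 fold change of 0.52 (adjusted p = 0.0620), BRD3 of -0.45 (adjusted p = 0.0515), HEXIM1 of 0.09 (adjusted p = 0.765) and MYC of 0.49 (adjusted p = 0.0692). Of 24 tested genes of the methionine cycle and its branches, 4 rose and 1 fell, the same number when adjusted over the list alone, and the list was not called (median -0.02, direction of the test up, adjusted p = 0.619). Genes of the list that rose included SLC3A2, a subunit of amino acid transporters, at 1.71. AHCY, which breaks down S-adenosylhomocysteine, fell by 0.45 on the log2 scale, a call lost with median-of-ratios scaling (adjusted p = 0.111) and without any FIDAS-5 library or vehicle replicate 2 or 3 (adjusted p = 0.0531 to 0.0746). Of 37 tested methyltransferases none rose and 8 fell, also 8 when adjusted over the list alone, among them EZH2 (-1.61), DNMT3B (-1.42), NSD2 (-0.98) and PRMT5 (-0.68). That list was called lower (adjusted p = 0.00635), but not with an estimated correlation (adjusted p = 0.683 with an estimated correlation).

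Genes of cell division fell together. Of 39 tested DNA replication genes 34 fell and none rose, or 37 when adjusted over the list alone, with a median log2 fold change of -1.19. The replicative helicase genes MCM7 and MCM5 changed by -1.65 and -1.68, and GINS1, a helicase partner, by -1.89. Of 32 mitosis genes 29 fell, or 32 when adjusted over the list alone (median -1.22), among them KIF20A (-1.42), TTK (-1.26) and AURKB (-1.21). Of 22 histone genes with polyadenylated or replication-independent transcripts 16 fell and none rose (median -1.55; also 16 when adjusted over the list alone). Histones made up several of the largest falls: HIST1H1D went from 61.6 ± 17.4 to 7.77 ± 2.47 TPM (log2 fold change -2.83, adjusted p = 1.32e-04), and HIST1H2BM and HIST3H2BB changed by -2.83 and -2.72. HIST1H2BB and HIST2H3A changed by -2.70 and -2.68. Histone genes are near-identical to each other, so reads may be split between them and single levels are uncertain. The 3 lists were called lower with adjusted p = 3.69e-23, 1.07e-18 and 7.33e-14, and their calls were lost with an estimated correlation (adjusted p = 0.144, 0.263 and 0.104 with an estimated correlation). Smaller falls were seen in ribosome biogenesis, with 8 of 37 genes lower, also 8 when adjusted over the list alone (median -0.37, adjusted p = 1.30e-04; adjusted p = 0.550 with an estimated correlation), and in ribosomal proteins, with 7 of 52 lower, or 5 when adjusted over the list alone (median -0.23, adjusted p = 3.37e-04; adjusted p = 0.683 with an estimated correlation). Short RNAs among the largest falls included MIR4448, at 23.2, 15.7 and 14.9 TPM in vehicle and 0, 0 and 2.69 TPM with FIDAS-5, and MIR548D2, at 38.0, 41.6 and 40.8 TPM in vehicle and 7.02, 3.25 and 0 TPM with FIDAS-5.

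Several lists of immune and early response genes were called higher. Of 20 tested interferon-stimulated genes 15 rose and none fell, or 17 when adjusted over the list alone (median 1.34, adjusted p = 7.33e-14; adjusted p = 0.104 with an estimated correlation). OAS1, an enzyme that senses double-stranded RNA, rose from 4.01 ± 0.445 to 38.3 ± 4.21 TPM (log2 fold change 2.97), and the antigen presentation genes TAP1, PSMB9 and PSMB8 rose by 2.84, 2.09 and 1.89. Of 14 NF-kappaB targets and chemokines 9 rose, the same number when adjusted over the list alone (median 1.01, adjusted p = 5.25e-06; adjusted p = 0.319 with an estimated correlation), among them CXCL8 (2.26), NFKB2 (1.59) and CXCL2 (1.33). Of 24 immediate early genes 11 rose, or 13 when adjusted over the list alone, with PHLDA1 at 2.13 and FOS at 1.46 (adjusted p = 1.21e-05; adjusted p = 0.360 with an estimated correlation). GDF15 led the targets of the stress factor ATF4, of which 8 of 29 rose and 1 fell, but that list was not called (adjusted p = 0.0515). Among p53 targets the cell cycle inhibitor CDKN1A rose by 2.71, with 7 of 19 higher and 1 lower (adjusted p = 0.190).

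Several lists of genes of liver metabolism and secretion were also called higher, as were lists of the lysosome and the matrix. Of 17 apolipoprotein and lipoprotein genes 11 rose and none fell, or 12 when adjusted over the list alone (median 0.72, adjusted p = 3.00e-07; adjusted p = 0.104 with an estimated correlation), with APOE at 1.88, APOM at 1.81 and APOC1 at 1.40. Of 21 genes of fatty acid oxidation and ketogenesis 12 rose, among them CREB3L3, a transcription factor of the liver, at 1.42, and HADH fell by 0.68 (13 higher when adjusted over the list alone; median 0.71, adjusted p = 7.67e-07; adjusted p = 0.141 with an estimated correlation). Of 20 xenobiotic metabolism genes 10 rose and none fell, or 11 when adjusted over the list alone, with the transporter ABCC3 at 2.20 (adjusted p = 6.36e-05; adjusted p = 0.355 with an estimated correlation). Of 21 targets of the oxidative stress factor NRF2 9 rose, with AKR1C1, AKR1C2 and OSGIN1 (2.02) in front, and NQO1 fell (11 higher when adjusted over the list alone; adjusted p = 9.02e-05; adjusted p = 0.420 with an estimated correlation). Of 6 tested AHR targets CYP1A1, CYP1B1 and TIPARP (2.59) rose and NQO1 fell by 0.47 (list adjusted p = 0.00411; adjusted p = 0.319 with an estimated correlation). The fall of NQO1 was not called after the GC trend was removed (adjusted p = 0.0536) nor without vehicle replicate 2, FIDAS-5 replicate 2 or 3 or JQ1 replicate 2 (adjusted p = 0.0533 to 0.0973). Of 26 secreted plasma proteins 13 rose and 2 fell, with SERPIND1 at 1.92 and TTR at 0.95 (14 higher and 3 lower when adjusted over the list alone; adjusted p = 7.91e-04; adjusted p = 0.454 with an estimated correlation). Of 32 autophagy and lysosome genes 17 rose and none fell, with the protease CTSD at 1.63 and the autophagy receptor SQSTM1 at 0.94 (20 higher and 1 lower when adjusted over the list alone; adjusted p = 1.77e-06; adjusted p = 0.355 with an estimated correlation). Bile acid genes, with NR0B2 at 2.02 (4 of 11 higher, 1 lower), mesenchymal and matrix genes, with FN1 at 1.63 (8 of 16 higher, 9 when adjusted over the list alone), and gluconeogenesis and urea cycle genes, with FAH at 1.29 (7 of 16 higher, 1 lower, 8 and 1 when adjusted over the list alone), had adjusted p = 0.00344, 0.00676 and 0.0176 (adjusted p = 0.319, 0.550 and 0.319 with an estimated correlation). The chaperone list of the endoplasmic reticulum, with HERPUD1 at 1.11 (4 of 24 higher, 3 when adjusted over the list alone), and the glycolysis and hypoxia list, with PDK1 at -1.56 (3 of 24 higher, 6 lower, 3 and 8 when adjusted over the list alone), lay near the threshold (adjusted p = 0.0427 and 0.0440; adjusted p = 0.751 and 0.458 with an estimated correlation). Of the markers of other cell types, 3 of 4 tested leukocyte markers rose (LYZ by 1.16, LCP1 by 1.08 and CD68 by 0.75, but not CD14), as did 1 of 3 fibroblast and endothelial markers (PECAM1 by 0.84) and 1 of 4 cholangiocyte markers (MUC1 by 0.88). None fell over all genes, and 1 fibroblast marker fell when adjusted over the list alone.

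Across all tested genes 1711 rose and 1031 fell with FIDAS-5 by limma at an adjusted p under 0.05, 2742 in all, of which 539 rose and 355 fell by at least 2-fold. The 3 FIDAS-5 libraries lay all above or all below the 3 vehicle libraries in 39.3% of genes, where chance gives 10%. Of 38 tested lists 14 were called higher and 7 lower, and none with an estimated correlation. The fold changes rose with transcript GC content (Spearman 0.37 across genes), and removing that trend gave 4382 genes, a step chosen after the data were seen. Quantile normalization moved the split to 1904 higher and 1756 lower, and the count fell to 1639 without vehicle replicate 3 and to 1640 without FIDAS-5 replicate 3. The number that rose was 1072, 1101 and 1092 without vehicle replicate 3, FIDAS-5 replicate 1 and FIDAS-5 replicate 3, and the number that fell was 567, 622 and 548 without vehicle replicate 3, FIDAS-5 replicate 2 and FIDAS-5 replicate 3. The chaperone list was not called without vehicle replicate 1 or 3 or FIDAS-5 replicate 1 (adjusted p = 0.133, 0.0659 and 0.108), nor the glycolysis list without vehicle replicate 1, FIDAS-5 replicate 1 or any JQ1 library (adjusted p = 0.0502 to 0.150). The glycolysis list was also lost with a pseudocount of 0.1, median-of-ratios scaling and protein-coding genes only (adjusted p = 0.0623, 0.101 and 0.0679). The gluconeogenesis and urea cycle list was lost with the stricter filter (adjusted p = 0.190) and with the GC trend removed (adjusted p = 0.119). The stricter filter also ended the calls of the matrix list (adjusted p = 0.0568) and the chaperone list (adjusted p = 0.0734). With fry the lists of chaperones, methyltransferases and ribosomal proteins were not called (adjusted p = 0.241, 0.0699 and 0.104). Fry called ATF4 targets, hepatocyte transcription factors and apoptosis genes higher, which camera did not call (adjusted p = 0.0261, 0.0327 and 0.0327 by fry). Lists not called included hepatocyte transcription factors (adjusted p = 0.0588), nuclear RNAs (adjusted p = 0.0720), serine and folate metabolism (adjusted p = 0.0789), polyamines (adjusted p = 0.177), cholesterol synthesis (adjusted p = 0.309) and complement and the acute phase response (adjusted p = 0.318).

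**Figure D3:**
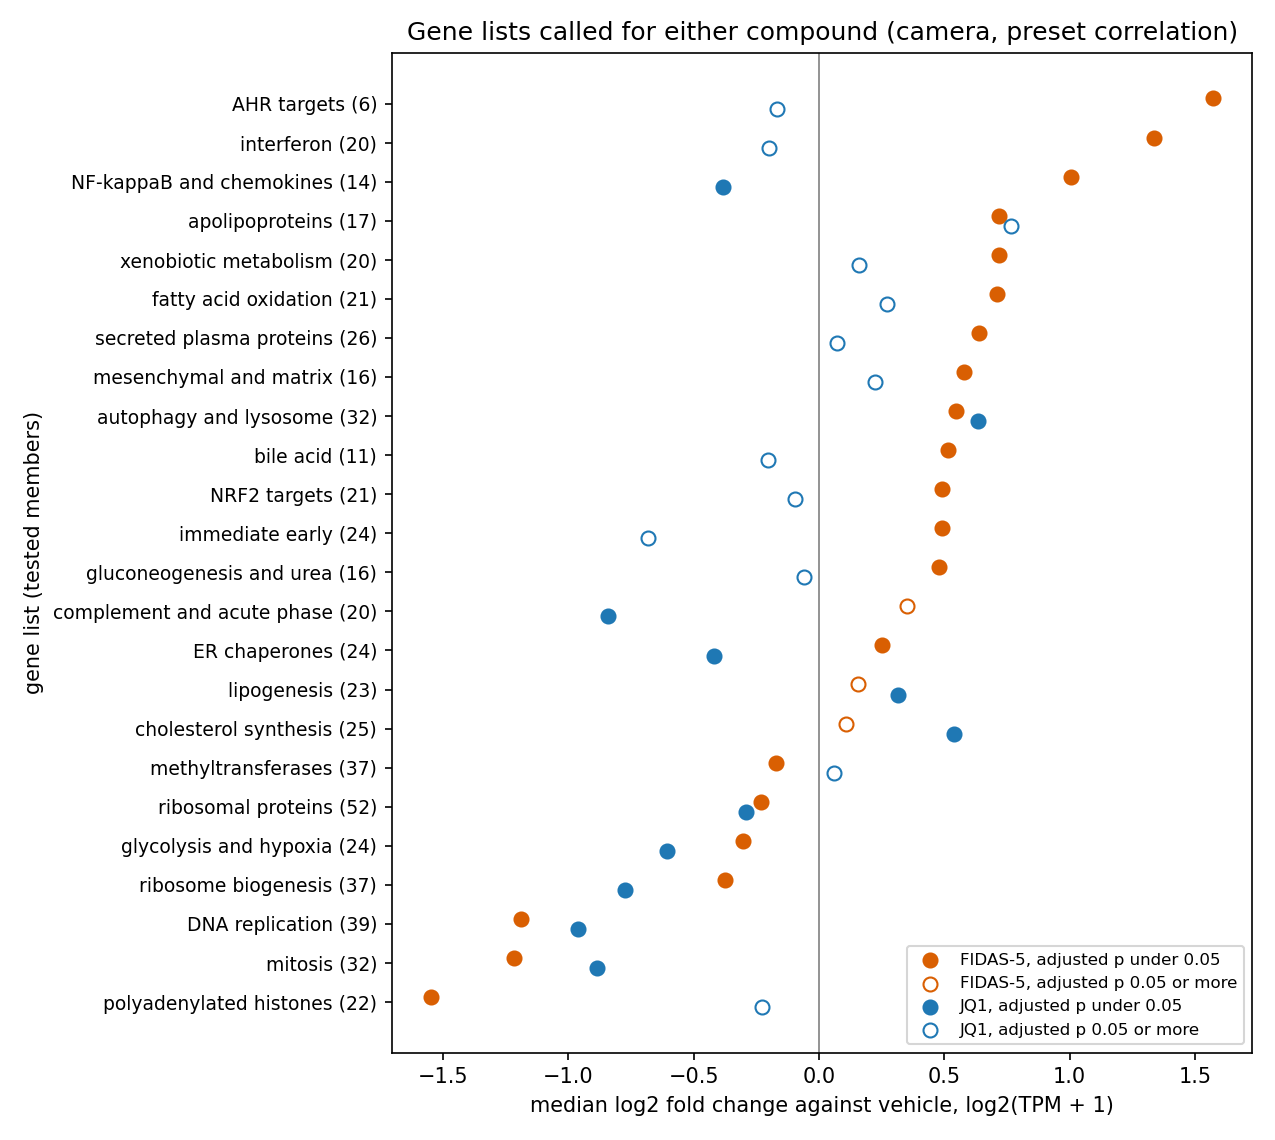
Median log2 fold change against vehicle of each gene list called for at least 1 compound, on the log2(TPM + 1) scale, with the number of tested members in brackets. Filled points have an adjusted p under 0.05 by camera with a preset correlation, open points do not; DNA replication lies at -1.19 with FIDAS-5 and -0.96 with JQ1, and the interferon list at 1.34 and -0.20.

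The comparison of JQ1 with vehicle asks which transcripts changed with BET inhibition. With JQ1, lists of ribosome biogenesis, cell division, glycolysis and the complement and acute phase response were called lower, and lists of the lysosome and of cholesterol synthesis higher, each with members that were not called. With an estimated correlation between genes none was called (smallest adjusted p = 0.840). The 3 fibrinogen genes, neighbours on chromosome 4, rose together: FGA (154583126 to 154590742) from 214 ± 53.7 to 2189 ± 275 TPM (SD, n = 3), a log2 fold change of 3.38 (SE 0.21, adjusted p = 1.55e-05), FGB by 3.26 and FGG by 3.25. The fibrinogen genes are not members of the complement and acute phase list, so its call does not cover them. TP53INP2, an autophagy factor, rose by 3.46, AMN, an endocytic receptor subunit, by 3.39 and the transcription factor MAF by 3.36. AADAC, an esterase of the liver on chromosome 3 (151814116 to 151828488), fell from 41.3 ± 9.45 to 0.987 ± 0.371 TPM (log2 fold change -4.41, SE 0.24, adjusted p = 1.05e-05). The bile acid transporter subunit SLC51B changed by -4.12, the acute phase protein ORM1 by -3.80, the gap junction gene GJA1 by -3.69, the secreted trefoil factor TFF1 by -3.58 and the neuropeptide GAL by -3.56. Histones HIST1H2BE, HIST1H4D and HIST1H2BM changed by -4.24, -4.17 and -3.68. MIR301B was at 21.6, 26.7 and 19.6 TPM in vehicle and listed at 0 in all 3 JQ1 libraries. MIR4284 was listed at 0 in all vehicle libraries and at 7.57, 31.3 and 5.22 TPM with JQ1, and MIR4663 at 0 in vehicle and 4.07, 9.71 and 11.6 TPM with JQ1. GOLGA2P5, a pseudogene, and MIR1827, which lie close together on chromosome 12 (100156391 to 100173343 and 100189884 to 100189949), rose by 3.06 and 3.43, the latter not with a pseudocount of 0.1 (adjusted p = 0.0616).

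HEXIM1, which inhibits the elongation factor P-TEFb, rose from 6.16 ± 0.153 to 23.3 ± 4.40 TPM (log2 fold change 1.75, SE 0.18, adjusted p = 1.30e-04); it lies on chromosome 17 from 45148475 to 45152099. BRD2 rose by 0.92 (adjusted p = 0.00300). BRD3 rose by 0.48 (adjusted p = 0.0248), a call lost without vehicle replicate 2 or 3 or JQ1 replicate 1 or 2 (adjusted p = 0.0589 to 0.0907). Of 15 genes of BET proteins and P-TEFb 5 rose and none fell, also 5 when adjusted over the list alone (adjusted p = 0.0765). MYC was at 8.69 ± 0.609 TPM in vehicle and 7.13 ± 0.825 TPM with JQ1 (log2 fold change -0.26, adjusted p = 0.256), while MYCN fell by 2.18 on the log2 scale. The list of MYC, MAX and partners was not called (3 of 13 higher, 3 lower, adjusted p = 0.940). MAT2A had a log2 fold change of -0.15 (adjusted p = 0.519), MAT2B of -0.54 (adjusted p = 0.129) and MAT1A of -0.02 (adjusted p = 0.919). Of 7 genes used elsewhere as readouts of BET inhibition 5 rose and CCR1 fell by 1.86 (adjusted p = 0.0679 for the list).

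Of 37 ribosome biogenesis genes 31 fell and none rose, or 33 when adjusted over the list alone (median -0.78), among them NOP16 (-1.53), RRS1 (-1.54), PPAN (-1.22) and the nucleolar methyltransferase FBL (-1.09). Of 32 mitosis genes 24 fell, or 28 when adjusted over the list alone (median -0.89), with PLK1 at -1.48 and KIF20A at -1.28. Of 39 DNA replication genes 26 fell, or 27 when adjusted over the list alone, and POLE rose by 0.62, a call lost without vehicle replicate 2 or 3 or JQ1 replicate 2 (adjusted p = 0.0549 to 0.0654; median -0.96; GINS1 -1.69, MCM3 -1.38). These 3 lists had adjusted p = 1.76e-09, 1.76e-09 and 5.30e-07, and no JQ1 list was called with an estimated correlation (each adjusted p = 0.840 with an estimated correlation for these 3). Of 24 genes of glycolysis and hypoxia 16 fell, or 17 when adjusted over the list alone, with LDHA, which makes lactate, at -2.01 and the pyruvate kinase PKM at -1.46, and PFKL, NDRG1 and ENO2 rose by 1.21, 1.13 and 0.55 (adjusted p = 0.00116; adjusted p = 0.840 with an estimated correlation). Of 20 complement and acute phase genes 12 fell, or 13 when adjusted over the list alone, and CFB rose by 0.59 (median -0.84, adjusted p = 1.45e-04; adjusted p = 0.840 with an estimated correlation). ORM1 and ORM2 (-3.06) are near-identical and C4BPA changed by -2.42. Of 14 NF-kappaB targets and chemokines 6 fell, also 6 when adjusted over the list alone, with CCL20 at -3.28, CXCL5 at -2.47 and the adhesion molecule ICAM1 at -2.44, and NFKBIZ rose by 1.92 (adjusted p = 0.0368; adjusted p = 0.933 with an estimated correlation).

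Of 32 autophagy and lysosome genes 20 rose, or 22 when adjusted over the list alone, with NEU1 at 1.97, CTSA at 1.71 and CTSB at 1.37, while TFEB, a transcription factor of lysosomal genes, and GPNMB fell by 0.83 and 0.95 (median 0.64, adjusted p = 5.20e-05; adjusted p = 0.840 with an estimated correlation). Of 25 cholesterol synthesis and uptake genes 10 rose and none fell, also 10 when adjusted over the list alone, with TM7SF2 at 2.69 and LSS at 2.25 (adjusted p = 0.00221; adjusted p = 0.840 with an estimated correlation). Of 23 lipogenesis genes 10 rose and 3 fell, the same when adjusted over the list alone, with FASN and DGAT1 both at 1.84 (adjusted p = 0.0368; adjusted p = 0.958 with an estimated correlation). Ribosomal proteins (12 of 52 lower, 3 higher, 11 and 3 when adjusted over the list alone) and chaperones of the endoplasmic reticulum (8 of 24 lower, 2 higher, the same when adjusted over the list alone, XBP1 -0.93) were called lower with adjusted p = 0.0224 and 0.0407 (adjusted p = 0.958 with an estimated correlation for both). Secreted plasma proteins moved both ways, 10 of 26 higher and 9 lower, or 11 and 10 when adjusted over the list alone (adjusted p = 0.940): albumin (ALB) rose from 1243 ± 323 to 3648 ± 1401 TPM and APOH, ITIH2 and TTR changed by -2.91, -2.32 and -1.73. Of 24 hepatocyte transcription factors 13 rose and 7 fell, or 14 and 8 when adjusted over the list alone (adjusted p = 0.403), with ONECUT1 at 1.72 and the bile acid receptor NR1H4 at -1.63. Of markers of other cell types LYZ fell by 3.10, PECAM1 by 1.97 and PDGFRA by 1.13, and KRT19 rose by 1.28. Not all called markers are named here. Among 4 tested leukocyte markers 2 fell and none rose. Among 3 fibroblast and endothelial markers 2 fell and 1 rose, and among 4 cholangiocyte markers 1 fell and 1 rose. Of 17 nuclear RNAs 2 rose and 5 fell, or 2 and 6 when adjusted over the list alone, and the list was not called (median -0.28, adjusted p = 0.295). Among them MALAT1 and NEAT1 rose by 2.17 and 1.98, and RPPH1 changed by -1.37.

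Across all tested genes 2582 rose and 2637 fell with JQ1 by limma, 5219 in all, of which 934 rose and 1009 fell by at least 2-fold. JQ1 and vehicle libraries did not overlap in 50.7% of genes, where chance gives 10%. Of 38 tested lists 3 were called higher and 8 lower. The NF-kappaB list was not called without vehicle replicate 1 (adjusted p = 0.0758), nor the lipogenesis list without JQ1 replicate 3 (adjusted p = 0.0519). The lipogenesis list was also not called with the replicate block (adjusted p = 0.0519), median-of-ratios scaling (adjusted p = 0.0668), protein-coding genes only (adjusted p = 0.0581), the stricter filter (adjusted p = 0.0596), the GC trend removed (adjusted p = 0.0818) or both replicates 3 left out (adjusted p = 0.0763). The same held for the ribosomal protein list without vehicle replicate 2 or JQ1 replicate 1 (adjusted p = 0.174 and 0.0701) and the chaperone list without vehicle replicate 1 or 2 or JQ1 replicate 3 (adjusted p = 0.0505, 0.0987 and 0.0885). The chaperone list was also lost with a pseudocount of 0.1 (adjusted p = 0.0541), the stricter filter (adjusted p = 0.0787), both replicates 3 left out (adjusted p = 0.0997) and fry (adjusted p = 0.145). The ribosomal protein list was lost with fry (adjusted p = 0.116).

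**Figure D4:**
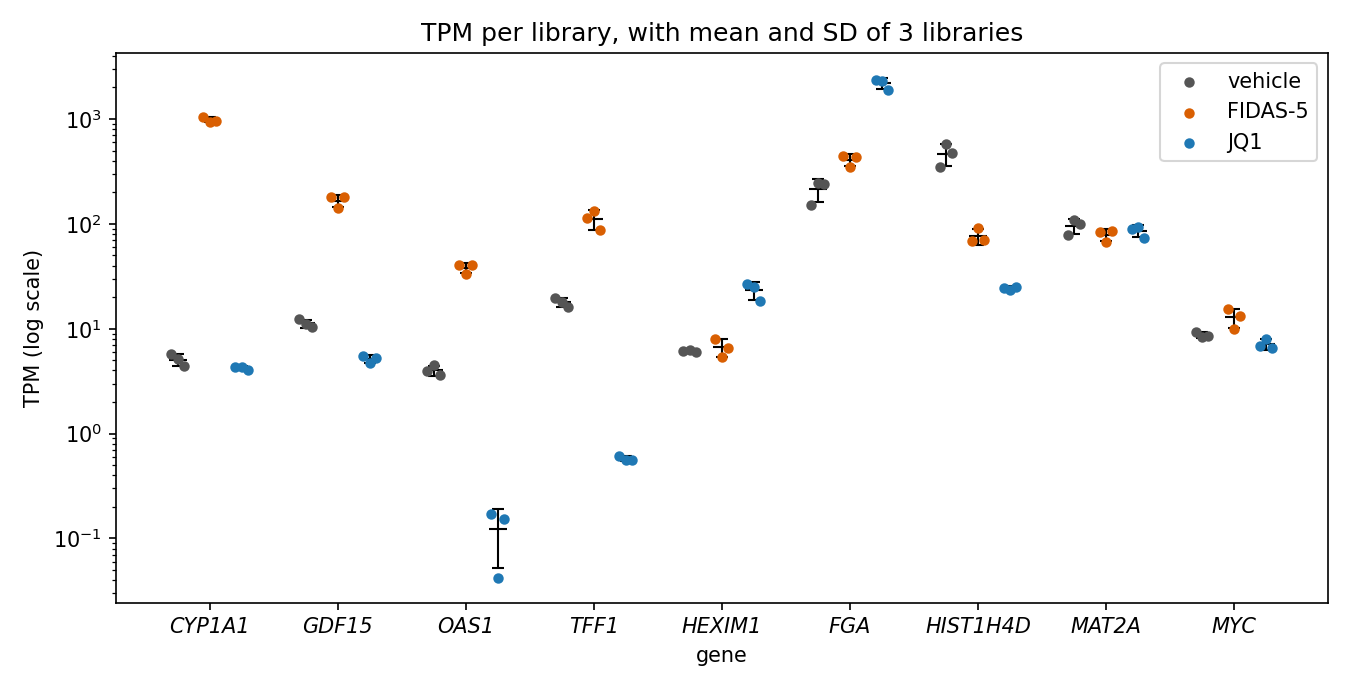
TPM per library on a log scale for 9 genes, with points coloured by group and bars giving the mean and SD of 3 libraries. CYP1A1 lies at 985 TPM with FIDAS-5 against 5.07 in vehicle and 4.23 with JQ1, FGA at 2189 with JQ1 against 214 in vehicle, and MAT2A at 95.5, 78.7 and 85.7 TPM in vehicle, FIDAS-5 and JQ1.

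The treated groups were then compared directly. Vehicle means do not enter that difference, but the vehicle libraries add to the estimate of the spread, and the 6 treated libraries alone gave 4625 genes. Lists of immune, stress and drug metabolism genes were lower with JQ1 than with FIDAS-5. Lists of histone genes with polyadenylated transcripts, cholesterol synthesis and DNA replication were higher. With an estimated correlation no list was called in this comparison (smallest adjusted p = 0.397). Of all 63 tested genes with a HIST symbol, a grouping made after the data were seen, 32 were higher with JQ1 than with FIDAS-5 and 10 lower (median 0.58). Those lower included HIST1H2BE (log2 difference -1.74, adjusted p = 1.69e-05) and HIST1H4D (-1.59, adjusted p = 3.33e-04). CYP1A1 was lower with JQ1 by a log2 difference of -7.56 (adjusted p = 8.26e-09), TFF1 by -6.13 (0.578 ± 0.0328 TPM against 112 ± 23.4), NAT8 by -5.63, AADAC by -5.45 and OAS1 by -5.12. PEG10, an imprinted gene, was higher with JQ1 by 3.50 (750 ± 347 TPM against 63.6 ± 28.2). MIR1827 and the small nuclear RNA RNVU1-4 were higher by 5.17 and 3.78, the latter with near-identical copies and not called with a pseudocount of 0.1 (adjusted p = 0.0542). MYC was lower with JQ1 than with FIDAS-5 (log2 difference -0.75, adjusted p = 0.00795), and HEXIM1 and BRD3 were higher by 1.66 and 0.93. MAT2A did not pass (log2 difference 0.12, SE 0.17, adjusted p = 0.629).

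Of 20 interferon-stimulated genes 14 were lower with JQ1 and none higher, also 14 when adjusted over the list alone (median -1.23, adjusted p = 1.20e-07; adjusted p = 0.397 with an estimated correlation). Also lower were 16 of 20 complement and acute phase genes, with 1 higher, or 16 and 4 when adjusted over the list alone (median -1.43, adjusted p = 2.56e-06; adjusted p = 0.461 with an estimated correlation) and 9 of 14 NF-kappaB targets, with 1 higher, or 10 and 1 when adjusted over the list alone (median -1.58, adjusted p = 6.12e-06; adjusted p = 0.461 with an estimated correlation). Of 24 immediate early genes 16 were lower and 3 higher, or 16 and 4 when adjusted over the list alone, and of 37 ribosome biogenesis genes 16 were lower and none higher, or 18 and none (adjusted p = 3.98e-05 and 4.54e-05; adjusted p = 0.575 and 0.657 with an estimated correlation). The polyadenylated histone list was higher, with 16 of 22 members higher and none lower, or 17 when adjusted over the list alone (median 1.03, adjusted p = 1.16e-07; adjusted p = 0.397 with an estimated correlation), and 15 of 39 DNA replication genes were higher and 2 lower, or 16 and 2 when adjusted over the list alone (adjusted p = 4.62e-04; adjusted p = 0.659 with an estimated correlation). Of 25 cholesterol genes 12 were higher and 2 lower, the same when adjusted over the list alone (adjusted p = 0.00541; adjusted p = 0.659 with an estimated correlation). Lists of chaperones, ATF4 targets, NRF2 targets, AHR targets, bile acid genes, xenobiotic metabolism and glycolysis were also lower with JQ1 (adjusted p = 5.78e-05 to 0.0147; adjusted p = 0.461 to 0.659 with an estimated correlation). In all, 2220 genes were higher and 2506 lower with JQ1, 4726 by limma, and 3 lists were called higher and 12 lower. With the stricter filter 2991 genes were called. The number higher was 1456 without FIDAS-5 replicate 2, 1469 without FIDAS-5 replicate 3, 1454 without JQ1 replicate 1, 1369 without JQ1 replicate 2 and 3393 after the GC trend was removed.

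Genes changed in the same direction by both compounds included members of lists of cell division and of the lysosome. Both lowered 26 of 39 DNA replication genes, 23 of 32 mitosis genes and 8 of 37 ribosome biogenesis genes, and both raised 13 of 32 autophagy and lysosome genes and 6 of 17 apolipoprotein genes. BMF, a pro-apoptotic member of the BCL2 family, rose by 2.61 with FIDAS-5 and 2.33 with JQ1, TP53INP2 by 2.44 and 3.46 and MAF by 2.06 and 3.36. The linker histone HIST1H1B changed by -2.64 and -3.02, HIST1H1D by -2.83 and -2.32 and HIST1H4D by -2.58 and -4.17. Other genes went opposite ways: the mucin-type glycosyltransferase GCNT3 rose by 2.44 with FIDAS-5 and changed by -2.67 with JQ1, TFF1 by 2.55 and -3.58, and NAT8 and NAT8B, which are near-identical, by 2.10 and -3.53 and by 2.12 and -2.05. MIR3189 lies inside GDF15 and moved with it (2.16 and -2.20), so their signals cannot be separated.

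In all, 1345 genes changed in the same direction with both compounds, 727 higher and 618 lower, where independent lists of these sizes would share 325 and 200. Another 341 rose with FIDAS-5 and fell with JQ1 (332 for independent lists), and 41 fell with FIDAS-5 and rose with JQ1 (196). Across genes the fold changes had a Pearson correlation of 0.345 and a Spearman correlation of 0.385, and a same sign in 64.0% of genes. All 3 lie inside the 95% ranges of 100 simulations of unchanged groups (-0.0736 to 0.918, -0.262 to 0.921 and 40.2 to 90.6%). The simulated groups shared simulated vehicle libraries and held no treatment effects, so these 3 values cannot tell whether the responses were shared. The covariance of the fold changes was 0.154, above the simulated 95% range of -0.00435 to 0.118. Its difference from the simulated median of 0.0350 was 0.119. The vehicle libraries were also split, 1 for one compound and 2 for the other, in all 6 ways, a test chosen after the data were seen. These splits gave 299 to 1075 shared genes, 2.28 to 3.88 times as many as independent lists (2.56 times with all libraries). The covariance was 0.0741 to 0.142 and the Pearson correlation 0.148 to 0.276, so part of the correlation may come from the shared controls, although fewer vehicle libraries also add noise. With an equal spread in all groups, a shared vehicle mean adds the residual variance divided by 3 to the covariance on average. That was 0.0457, which leaves 0.109 of the 0.154. Sharing beyond independent lists remained in every split. Calls of both compounds used 1 estimate of the spread per gene, however, which can make calls coincide. Opposite calls were not counted in the splits, so that contribution was not measured there. Fold changes of both compounds rose with transcript GC content (Spearman 0.37 for FIDAS-5 and 0.22 for JQ1 across genes). The splits were made without removing that trend, so they do not test whether it adds to the sharing. The count of 1345 fell to 735 without vehicle replicate 3 and to 768 without FIDAS-5 replicate 3, and was 2210 after the GC trend was removed. These counts move with the number of genes called, which was 4382 for FIDAS-5 and 7125 for JQ1 after that removal. The overlap of independent lists was not computed for these settings. The counts alone therefore do not show whether sharing beyond it grew or shrank.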

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

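The alternatives with protein-coding genes only, with the GC trend removed with FIDAS-5 and JQ1 replicates 3 left out together and with split vehicle libraries were chosen only after results were seen. Only RNR1 and RNR2 match the mitochondrial chromosome, at most 94.3 and 51.4 TPM. Leaving them out moved next to nothing (5222 genes with JQ1) and tests nothing. With the replicate block, 2891 genes changed with FIDAS-5, 5544 with JQ1 and 5052 differed between the compounds; the labels do not say that equal numbers share a culture or a day, and correlations of departures between libraries of the same number were 0.260, 0.102 and 0.422 between the compounds (other numbers -0.350 to 0.179) and -0.0765 to 0.160 with vehicle. Of the 9 libraries 6 correlated best with their own number, so a pairing is neither shown nor excluded.

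With the GC trend removed, 4382 genes changed with FIDAS-5 (1988 lower), 3393 were higher with JQ1 than with FIDAS-5, and 2210 changed in the same direction with both. The overlap of independent lists was not computed for that last count. With FIDAS-5 set against vehicle 1, 2 or 3 and JQ1 against the others, 410, 1075 and 299 genes changed with both (correlation 0.148, 0.273 and 0.248). With JQ1 against vehicle 1, 2 or 3 and FIDAS-5 against the others it was 745, 867 and 518 (correlation 0.202, 0.213 and 0.276); fewer vehicle libraries lower the counts. Removing the trend lowered the median standard error for FIDAS-5 from 0.188 to 0.133. Quantile normalization gave 1756 genes lower with FIDAS-5. The stricter filter, which tests fewer genes (8619), gave 2991 genes that differed between the compounds, 1325 higher and 1666 lower. The correlation of the fold changes was 0.298 with a pseudocount of 0.1, 0.2999 with protein-coding genes only, 0.304 with the GC trend removed and 0.301 with replicates 3 left out; the cause was not tested. With an estimated correlation 0 lists were called for FIDAS-5 and 0 for JQ1 (smallest adjusted p = 0.104 and 0.840), and fry, which tests whether a list's genes move on balance one way, called 21 and 18, of which 18 and 9 were also called by camera with the preset correlation.

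Leaving out each library in turn gave 1639 to 3290 genes for FIDAS-5 (1072 to 1858 higher, 548 to 1445 lower), 3924 to 5337 for JQ1, 3394 to 5435 between the compounds (1369 to 3246 higher), and 735 to 1503 for both compounds. The correlation ranged from 0.295 to 0.424, and 19 to 23 lists were called for FIDAS-5 and 9 to 12 for JQ1. HEXIM1 with FIDAS-5, which was not called, ranged from -0.0362 without FIDAS-5 replicate 1 to 0.214. MAT1A with JQ1, which was not called, ranged from -0.0696 to 0.0555 without vehicle replicate 2, and was 0.0122 with replicates 3 left out and without JQ1 replicate 3; the cause was not tested. Of 8012 further values of single genes, 7778 kept their direction and side of the threshold, 199 were no longer called, 31 became called and 4 changed sign, as given above for HEXIM1 and MAT1A. Most of these genes were picked for large changes or the smallest adjusted p, so most were likely to keep their call. Of all 2742 genes called for FIDAS-5, 1618 kept their call without vehicle replicate 3 and 1614 without FIDAS-5 replicate 3. These were the fewest when a library was left out. Depth limits cannot be given, since TPM keeps no counts.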

Other observations

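The groupings by gene symbol in the first paragraph were chosen only after results were seen, as were the tests of poly(A) capture, fewer cells copying DNA, drug metabolism, the aryl hydrocarbon receptor and a batch shared by libraries numbered 3, and the split counts after GC removal. Tested genes were grouped into 213 families of at least 8 symbols, and camera was run on them with a preset correlation; with an estimated correlation none was called (each adjusted p at least 0.993). With FIDAS-5, 12 of 23 cytochrome P450 genes rose and none fell (median 0.63, adjusted p = 6.80e-06), as did 7 of 9 receptors of the tumour necrosis factor family (median 0.77, adjusted p = 3.11e-04). Nucleoporins were lower, with 7 of 22 lower and 1 higher (median -0.65, adjusted p = 3.11e-04). With JQ1, 30 of 51 proteins of the large mitochondrial ribosomal subunit fell and 1 rose (median -0.57, adjusted p = 5.88e-06), among them MRPL11 (-2.04) and MRPL3 (-1.75). Of 11 proteasome beta subunits 7 fell (median -0.55, adjusted p = 0.0242), with PSMB6 at -1.25. Small nucleolar RNAs of the C/D class fell in 55 of 184 cases with JQ1 and 25 with FIDAS-5 (median -0.66 and -0.43, adjusted p = 0.00247 and 0.00115).

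Of 63 tested genes with a HIST symbol 58 fell with FIDAS-5 and none rose (median -1.92), and with JQ1 50 fell and 3 rose (median -1.47). A shift in the RNAs that share the TPM total is argued against: the highest of 4 medians, under median-of-ratios scaling and protein-coding genes only with each compound, was -1.46, and quantile normalization gave -1.88 with FIDAS-5 and -1.33 with JQ1. For lower capture of RNA without a poly(A) tail, small structural RNAs (without microRNAs and ribosomal RNA) had medians of -0.25 and -0.49, at least 0.974 above those of the histones. With FIDAS-5 this argues against it, and the list of histones with polyadenylated transcripts fell too (median -1.55). With JQ1 the values conflict, since 7 of the 22 members of that list rose and 7 fell (median -0.23, adjusted p = 0.535 by camera, 0.0394 by fry with direction down). Lower capture with JQ1 was therefore neither shown nor excluded. Fewer cells copying DNA may contribute, since the DNA replication list had medians of -1.19 and -0.96. That test cannot show whether cell numbers or transcription per cell changed, and reads shared between near-identical histone genes were not tested.

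CYP1A1, CYP1B1 and TIPARP rose with FIDAS-5. The scaling of the TPM is argued against, since the smallest log2 change of the 3 genes over 3 scalings was 2.57. A general rise of drug metabolism genes may contribute, since 50% of the xenobiotic list rose (median 0.72), although that list moved far less than CYP1A1. For activity of the aryl hydrocarbon receptor, 0 of the 3 other tested targets rose, which is too few to decide.

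FIDAS-5 replicate 3 and JQ1 replicate 3 departed from their group means together (correlation 0.42 across genes). Transcript length is argued against (Spearman -0.0680 and -0.0920). For a batch shared by the 3 libraries numbered 3 the values conflict: correlations with vehicle replicate 3 were at most 0.00539, but RNR1, matched to mitochondrial ribosomal RNA, was at 11.1, 19.1 and 94.3 TPM in these libraries and at most 3.92 in the others, and RNR2 was likewise higher in all 3. Such a batch cannot be told apart from other causes. GC content may account for part of it, with Spearman correlations of 0.555 and 0.641, and the correlation between the libraries was 0.27 after the GC trend was removed. No biological explanation was tested.

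Each comparison of 3 libraries with 3 allows 10 splits, too few for a share under 0.05. All splits other than the real one mix the groups, so a difference between the groups adds to their spread and lowers their calls. Their counts are therefore not a rate of false calls. For FIDAS-5 1 split, the real one, gave as many as 2742 genes (highest other 6), for JQ1 1 split gave 5219 (highest other 7), and between the compounds 1 split gave 4726 (highest other 1050). That other split set FIDAS-5 replicate 1 and JQ1 replicates 1 and 2 against the rest and called 3 genes after the GC trend was removed. It points to a structure of the samples along that trend.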
